A study of Mus musculus with 6 samples.

How the data were processed

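The deposited table held raw read counts per gene for 6 mouse bone marrow libraries made by poly(A) selection, 3 WT and 3 KO. Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b, and featureCounts of Subread 1.5.2, with GRCm38 as the genome build. The order and settings of these tools, the annotation release, the strand setting and the treatment of reads matching several places are not given in the sources used here. The labels give bone marrow as the source, whereas the extraction text per the labels names white adipose tissue. Samples were grouped by genotype as the labels state it, and HFSC is used as the labels give it.

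Gene identifiers were matched to GENCODE M21 (GRCm38) for symbols, coordinates, exon lengths, GC content and 3' UTRs. Of 49315 identifiers 48970 had a symbol, and those without one held 0.0461% of counts. An annotated 3' UTR was found for 20857 genes. Counts were tested as deposited with edgeR 4.0.16 (R 4.3.3) using TMM scaling, filterByExpr by group and the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Scaling factors lay between 0.948 and 1.04. Fold changes are log2, KO minus WT, with standard errors. CPM values of genes are counts scaled by the library total times its TMM factor, except for the floors and the Xist and Y-linked values, which use the total alone. The smallest p that an exact permutation of 3 against 3 libraries can give is 0.1, so single genes were tested only in models fitted across all genes.

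Gene lists for 30 cell types and pathways were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether the genes of a set move on balance in a single direction. Of the 30 lists 12 passed with the preset correlation, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 4 in fry. Some lists share genes, such as Klf4 and Nr4a1 in the monocyte and immediate early lists and Ccl2 in the angiogenic and NF-kB lists. Intervals of list medians resample the genes of a list and do not measure the spread between libraries. Genes with an 8mer or 7mer miR-181a/b-5p site were compared with genes without a 6mer and with 10000 random lists of such genes matched in 10 bins of expression and 5 of 3' UTR length. The lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Cxcr4 and the genes of the deleted locus, then up to 10 higher and 10 lower genes with the largest change among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between groups, and up to 4 members of each list with the smallest p. Predicted genes, pseudogenes and antigen receptor segments were left out of the ranking.

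The procedure was tested on simulated counts for KO against WT with 200 changed genes. At a 1.5-fold change 22.0% were recovered with a mean of 7.2 false calls (16526 genes), and at a 2-fold change 59.9% with 13.6 false calls (16564 genes). The share of false calls was thus above the nominal level. A shift of 0.1 in genes with 8mer sites was called in 10 of 10 draws and a shift of 0 in 0 of 10. A fall of 0.5 in the erythroid list was called in 5 of 5 draws, and 2 other lists were called over 5 draws without any change. Counts were simulated independently for each gene. These draws therefore cannot show how correlation between genes affects the list and site tests.

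Alternatives were DESeq2 size factors, library totals only, no filter on low counts, a mean log2 CPM of at least 1, the replicate number as a block, each library left out in turn, haemoglobin, mitochondrial and immunoglobulin genes left out, DESeq2 1.42.0 and limma 3.58.1 with sample quality weights. A covariate for libraries with Xist above 1 CPM and removal of each library's trend on exon length and GC content were added after seeing the data. Total counts per library were 34000323, 40034773 and 40359093 in WT and 33861440, 36394812 and 39566582 in KO. Floors of 3 counts cover counting error only. The rules for reading some tests were also changed after their values were seen, and each such change is stated beside its value.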

Results

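Messenger RNA was profiled in mouse bone marrow from animals kept on the HFSC diet and subjected to hindlimb ischemia, a surgical block of blood flow to a leg. The groups were 3 libraries from animals with a floxed, undeleted miR-181a2b2 locus (WT, replicates 1, 3 and 4) and 3 libraries from animals lacking it (KO, replicates 2, 3 and 4). miR-181a and miR-181b are microRNAs, short RNAs that lower the level or translation of messenger RNAs carrying matching sites. Total counts lay between 33861440 (KO replicate 2) and 40359093 (WT replicate 4), so that 3 counts, the most a count of 0 allows, corresponded to between 0.0743 and 0.0886 CPM, the count of a gene scaled to a common library total. Transcripts of marrow cells were abundant. S100a8 and S100a9, which encode a calcium-binding protein complex of neutrophils, together took between 2.01% and 2.51% of counts in the WT libraries and between 2.98% and 3.89% in the KO libraries. Haemoglobin genes took between 1.04% and 2.78% of counts over the 6 libraries. The first principal component held 40.05% of the variance and placed the WT libraries at -21.9, -25.6 and -27.5 and the KO libraries at 9.09, 12.02 and 53.9, the last being KO replicate 4. No pair of libraries was alike within sampling noise, with a chi-square per gene of at least 26.7 in each pair. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

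The deleted locus was examined first. On chromosome 2 (GRCm38), Mir181a-2 at 38852735 to 38852810 and Mir181b-2 at 38853830 to 38853918 had 0 counts in all 6 libraries. Libraries made by poly(A) selection capture such short precursors poorly, and these counts therefore neither support nor contradict the genotype labels. Nr6a1os, an antisense transcript that ends just before Mir181a-2 (38823257 to 38852370), had 44 counts summed over the WT libraries and 40 over the KO libraries. Nr6a1, the nuclear receptor gene on the opposite strand that spans the microRNAs (38723370 to 38927688), had a log2 fold change (KO minus WT) of 0.28 ± 0.25 (SE, 3 against 3 libraries, edgeR adjusted p = 0.533). Gm44144, which overlaps Mir181b-2 on the opposite strand, had 9 and 6 counts and was not tested. 5730507A11Rik, an unclassified transcript downstream of the microRNAs on their strand (38862163 to 38865533), had 67 counts in WT and 22 in KO. Its log2 fold change was -1.44 ± 0.45 (SE), with a 95% interval from -2.45 to -0.44, and did not pass the threshold over all genes (edgeR adjusted p = 0.103). The strand setting of the authors' counting is not given in the sources used here, so reads from Nr6a1 and its antisense partners cannot be told apart.

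The series title names CXCR4, the chemokine receptor that holds blood-forming cells in the marrow, and Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293) was therefore compared next. Its level was 365 ± 42.6 CPM in WT and 397 ± 35.8 CPM in KO (SD, n = 3 each). The log2 fold change of 0.12 ± 0.12 (SE) was within the spread between libraries (edgeR adjusted p = 0.563). Its 95% interval ran from -0.14 to 0.38, that is from 0.907 to 1.30 times the WT level. Of the 20 measured genes of the CXCR4 and cell retention list, 1 fell, 0 rose and 19 did not pass the test in edgeR. DESeq2 called 5 higher and 3 lower and limma 2 higher and 2 lower, and at an unadjusted p under 0.05 edgeR gave 7 higher and 3 lower. With adjustment over the list alone 3 rose and 2 fell. In edgeR 2 fell without KO replicate 2 and 2 without KO replicate 3, and 1 rose without WT replicate 4. The gene that fell in edgeR over all libraries was Rgs1, a brake on signalling through chemokine receptors. It lay at 40.6 ± 1.45 CPM in WT and 9.78 ± 1.27 CPM in KO (SD). Arrb2, a receptor-internalising arrestin, had a log2 fold change of 0.52 (adjusted p = 0.0592), Selplg, a selectin ligand, of 0.44 (adjusted p = 0.0724) and Itga4, an integrin subunit, of -0.59 (adjusted p = 0.0809). The list as a group did not move in a common direction relative to other genes (camera adjusted p = 0.725). Its genes moved both ways, and fry for changes in either direction gave an unadjusted p = 3.7e-05. The median log2 fold change of the list was 0.18 and its mean -0.04.

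Genes were ranked genome-wide among those past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes, pseudogenes and antigen receptor segments. The 10 that fell furthest in KO marrow by this rule are given first. Fosb, a subunit of the AP-1 transcription factor, was 8.70-fold lower, at 630 ± 86.6 CPM in WT and 72.4 ± 26.9 CPM in KO (SD, n = 3 each). Ccl2, a chemokine that attracts monocytes, was 6.53-fold lower, Atf3, a stress-induced transcription factor, 4.64-fold, and Egr1, a growth-factor-induced transcription factor, 4.24-fold. Rgs1 was 4.15-fold lower, Jun, another AP-1 subunit, 3.85-fold, Cd69, a leukocyte activation marker, 3.82-fold and Plk2, a kinase, 3.77-fold. Hist1h2bg, a core histone gene, was 3.66-fold lower and Hspa1a, an inducible heat shock protein, 3.45-fold. Both have near-identical copies, and their values are uncertain because the treatment of reads that match several copies is not given in the sources used here.

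The 10 genes that rose most by the same rule included Cxcl9, an interferon-induced chemokine, at 1.66 ± 0.594 CPM in WT and 4.37 ± 0.420 CPM in KO (SD, n = 3 each), a 2.63-fold difference. Fkbp5, a co-chaperone of the glucocorticoid receptor, was 2.42-fold higher, at 92.6 ± 5.73 CPM in WT and 224 ± 40.4 CPM in KO. Ly6c1 was 2.22-fold higher and is uncertain because of its close paralog Ly6c2. Colec12, a scavenger receptor, was 1.95-fold higher, Crispld2 1.93-fold, Banp 1.87-fold, Rdh12, a retinol dehydrogenase, 1.86-fold and Wfdc21 1.84-fold. Sla, an adaptor of antigen receptor signalling, was 1.77-fold higher and Adtrp 1.76-fold. Each of these 20 genes had edgeR adjusted p values below the threshold of 0.05, between 0.000177 for Rgs1 and 0.0474 for Adtrp, and no overlap between the groups. Fosb, Ccl2, Atf3, Rgs1, Jun, Cd69, Plk2, Fkbp5 and Sla kept their calls whichever library was left out. Of the others, Rdh12 lost its call without KO replicate 4, Hist1h2bg without WT replicate 1, 3 or 4, Banp without WT replicate 1 or KO replicate 4, and Egr1, Cxcl9, Ly6c1, Colec12, Crispld2, Wfdc21, Adtrp and Hspa1a without WT replicate 1, without KO replicate 4 and without at least 1 further library.

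Over all 16956 genes tested, 417 passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), of which 159 were higher and 258 lower in KO. At an unadjusted p under 0.05 there were 4057. The lower genes had a median exon length of 5974 bases and the higher genes of 2320 bases, against 3781 bases over all genes tested. The share of higher genes was 38.1%, but 17.8% (87 higher, 403 lower) with library totals as the only scaling, 48.6% (171 higher, 181 lower) after removal of each library's trend on exon length and GC content, and 52.2% with DESeq2. The number of genes depended on single libraries, being 33 without WT replicate 1, 199 without WT replicate 3, 37 without WT replicate 4, 920 without KO replicate 3 and 32 without KO replicate 4, and it was 1492 with no filter on low counts, 1641 with DESeq2, 1057 with limma and 209 with Xist-containing libraries as a covariate. In all 6 fits that left out 1 library, 21 of the 417 genes were called. The 18 lower ones included Rgs1, Atf3, Ccl2, Nfkbiz, Jun, Cd69, Plk2, Tnfaip3, Fosb and Fos, and the 3 higher ones were Fkbp5, Dgat2 and Sla. Dgat2, a triglyceride-synthesis enzyme, was named after its values were seen.

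**Figure D1:**
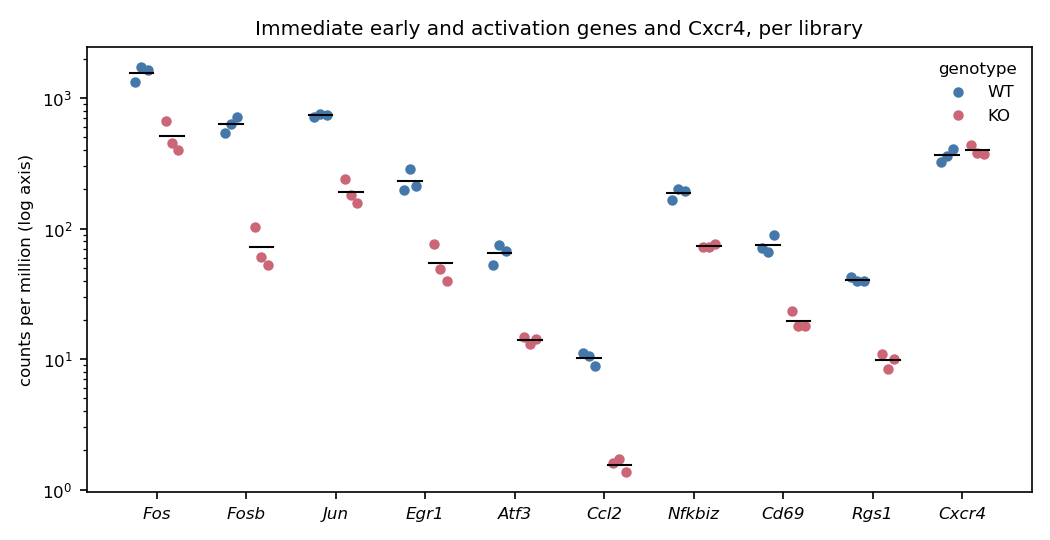
CPM on a log axis for 10 genes in each of the 3 WT (blue) and 3 KO (red) libraries, with a line at each group's mean. For the 9 genes other than Cxcr4 every KO library lay below every WT library, for example Fosb at 630 CPM in WT and 72.4 CPM in KO on average, while Cxcr4 lay at 365 and 397 CPM.

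The immediate early genes, which are transcribed within minutes of a stimulus, fell as a group. Their list was among those set beforehand to check RNA quality, other tissue and sample identity. Of 18 measured, 14 fell, 0 rose and 4 did not pass the test, and with adjustment over the list alone all 18 fell. DESeq2 and limma called 17 each as lower. Their median log2 fold change was -1.23. Beyond Fosb, Atf3, Jun and Egr1, Fos fell from 1563 ± 212 CPM to 509 ± 141 CPM (SD, n = 3 each) and Egr2 by 2.07 on the log2 scale. The list passed against all other genes (camera adjusted p = 4.5e-52) and in fry (adjusted p = 0.0156), but the call was lost with an adjusted p = 0.0992 with an estimated correlation. The number that fell was 7 without WT replicate 1, 9 without WT replicate 3, 7 without WT replicate 4 and 6 without KO replicate 4.

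NF-kB targets and inflammatory cytokines were also lower. Of 20 measured, 8 fell, 0 rose and 12 did not pass, and over the list alone 9 fell and 1 rose. DESeq2 called 8 lower and 1 higher, and limma 8 lower. Ccl2 led, followed by Nfkbiz, an inducible regulator of cytokine genes, at 186 ± 18.5 CPM in WT and 73.1 ± 2.13 CPM in KO (SD, n = 3 each). Tnfaip3, which restrains NF-kB signalling, fell by 1.07 and Osm, which encodes the cytokine oncostatin M, by 0.92 on the log2 scale. The median log2 fold change was -0.44 (camera adjusted p = 4.6e-16, fry adjusted p = 0.0109, adjusted p = 0.0992 with an estimated correlation). The number that fell was 5 without WT replicate 1 and 5 without KO replicate 4.

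Neutrophil genes were higher in KO marrow. Of 12 primary granule and promyelocyte genes, 5 rose, 0 fell and 7 did not pass, and over the list alone 11 rose. They included Elane, neutrophil elastase, at 924 ± 27.8 CPM in WT and 1379 ± 128 CPM in KO (SD, n = 3 each), Serpinb1a, its inhibitor, with a log2 fold change of 0.70, and Cebpe and Gfi1, transcription factors of granulocyte development, with 0.68 and 0.56. The median was 0.57 (camera adjusted p = 4.3e-12, fry adjusted p = 0.0377, adjusted p = 0.196 with an estimated correlation). The number that rose was 0 without WT replicate 1, 0 without WT replicate 3, 0 without WT replicate 4, 8 without KO replicate 2, where Gfi1 lost its call (adjusted p = 0.0518), 0 without KO replicate 4, 2 with the Xist covariate and 2 after removal of the length and GC trend. DESeq2 called 11 and limma 8 as higher.

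Of 20 late neutrophil genes, 4 rose, 0 fell and 16 did not pass, and over the list alone 14 rose. S100a8 rose from 9551 ± 1180 CPM to 16072 ± 2656 CPM (SD, n = 3 each), and Camp, an antimicrobial peptide, Chil3, a chitinase-like protein, and Wfdc21 had log2 fold changes of 0.73, 0.68 and 0.88. The median was 0.49 (camera adjusted p = 5.4e-11, adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.115). Camp lost its call without WT replicate 3 or KO replicate 2 too (adjusted p = 0.0546 and 0.0573), and Wfdc21 without WT replicate 3. The number that rose was 0 without WT replicate 1, 0 without WT replicate 4, 0 without KO replicate 4, 1 with the Xist covariate and 0 after removal of the length and GC trend, while DESeq2 gave 14 and limma 11.

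Erythroid and B cell genes were lower in KO marrow on average, with overlap between the libraries of both groups. Of 24 erythroid genes, 3 fell, 0 rose and 21 did not pass, and over the list alone 5 fell. DESeq2 called 6 and limma 4 as lower. The 3 included Sptb, a part of the red cell skeleton, and Ermap, a red cell membrane protein, with log2 fold changes of -0.85 and -0.69. The median was -0.33 (camera adjusted p = 3.1e-07, adjusted p = 0.604 with an estimated correlation, fry adjusted p = 0.259). The number that fell was 0 without WT replicate 1, 5 without WT replicate 3, 0 without WT replicate 4 and 0 without KO replicate 4, and the median moved to -0.17 without WT replicate 1, -0.55 without WT replicate 3 and -0.53 without KO replicate 2. Of 14 mature B cell genes, 0 passed in edgeR, 7 were lower at an unadjusted p under 0.05, and DESeq2 called 5 and limma 0. Cr2, a complement receptor, had a log2 fold change of -1.14 ± 0.29 and Ms4a1, which encodes CD20, of -1.03 ± 0.27 (SE). The median was -0.83 (camera adjusted p = 0.000676, adjusted p = 0.604 with an estimated correlation, fry adjusted p = 0.259), and -0.46 without WT replicate 1. The number that fell was 3 without WT replicate 3 and 1 without KO replicate 2. Of 18 B cell precursor genes, 0 passed in edgeR, 0 at an unadjusted p under 0.05, and 0 in DESeq2 or limma. Their median was -0.58 (camera adjusted p = 0.00176, adjusted p = 0.817 with an estimated correlation), and all 18 had negative values, among them Bach2 at -1.23 and Blnk at -0.61. The median depended on single libraries, being -1.40 without KO replicate 2, where 13 of these fell, -0.28 without KO replicate 3, where the camera call was lost (adjusted p = 0.0831), -0.36 without WT replicate 4 and -0.35 without KO replicate 4.

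**Figure D2:**
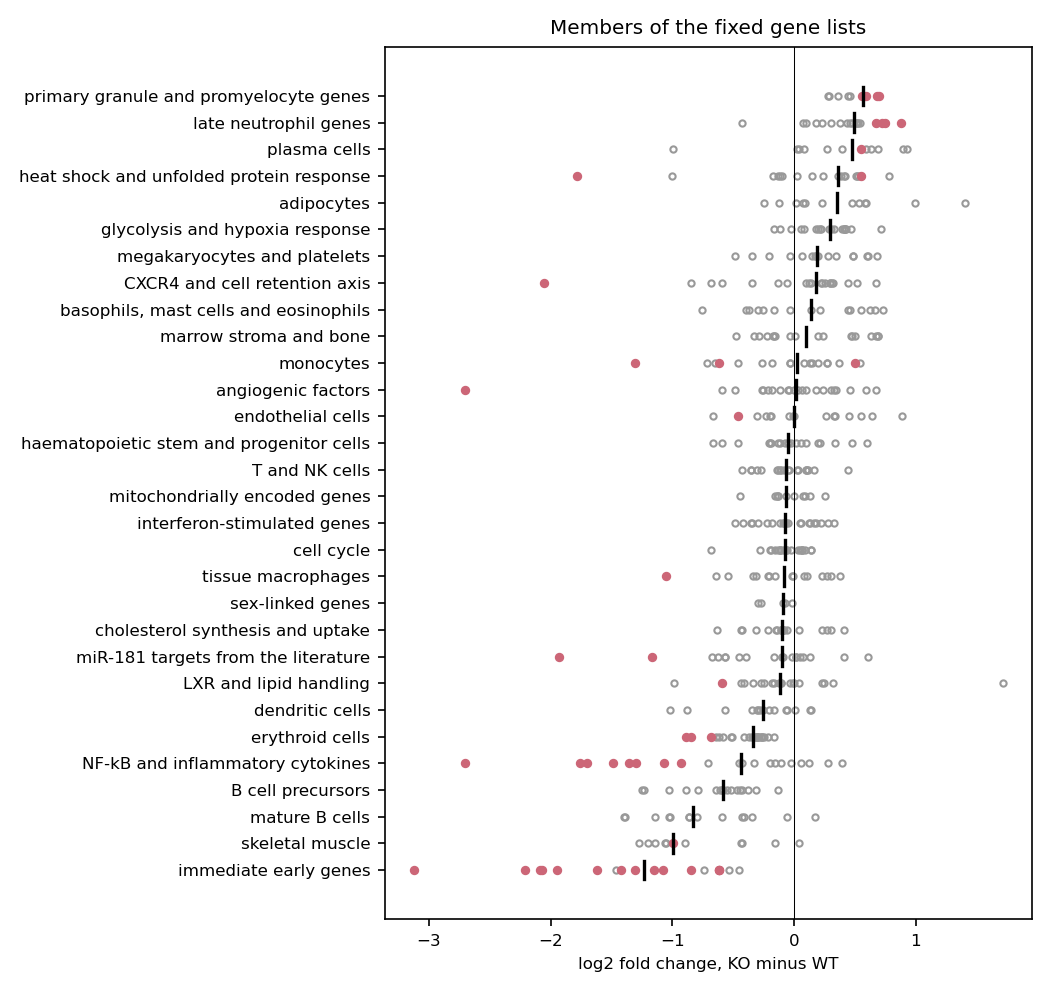
Log2 fold change (KO minus WT, x axis) of each measured member of the 30 fixed gene lists (y axis), with filled red points for genes past the adjusted threshold of 0.05, open grey points for the others and a black tick at the median of each list. The immediate early list had the lowest median (-1.23) and the primary granule list the highest (0.57).

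Further lists passed camera. Plasma cell genes had a median of 0.47 over 12 genes (camera adjusted p = 0.00118, adjusted p = 0.209 with an estimated correlation, fry adjusted p = 0.056), of which Xbp1, a transcription factor of secretory cells, rose, a call lost without WT replicate 1, 3 or 4 and without KO replicate 4. DESeq2 called 5 and limma 1 as higher. With immunoglobulin, haemoglobin and mitochondrial genes left out the median was 0.27 over 9 genes (camera adjusted p = 0.0241). Glycolysis and hypoxia genes had a median of 0.30 over 20 genes (camera adjusted p = 0.000244, adjusted p = 0.604 with an estimated correlation), with 0 past the threshold in edgeR, 10 higher at an unadjusted p under 0.05, 6 in DESeq2 and 4 in limma. Aldoa and Gapdh, glycolytic enzymes, had log2 fold changes of 0.47 and 0.41. Skeletal muscle genes, included to detect tissue carried into the sample, had a median of -0.99 over 11 genes (camera adjusted p = 0.0048, adjusted p = 0.604 with an estimated correlation). Only Tnnt3, a troponin, passed, at 2.80 ± 0.438 CPM in WT and 1.41 ± 0.0692 CPM in KO (SD), and it lost its call in each of the 6 fits that left out 1 library. Adipocyte genes, measured because the extraction label names white adipose tissue, had a median of 0.35 over 12 genes (camera adjusted p = 0.0106, adjusted p = 0.209 with an estimated correlation). Of these 0 passed in edgeR, 4 were higher at an unadjusted p under 0.05, and DESeq2 and limma called 1 each, while the camera call was lost without WT replicate 3 (adjusted p = 0.0546) and without KO replicate 2 (adjusted p = 0.0777). Adipoq, the adipocyte hormone gene, lay at 3.61 ± 1.06 CPM in WT and 5.43 ± 1.12 CPM in KO.

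The remaining cell type lists did not pass camera over all 6 libraries. Of 18 monocyte genes, Klf4 and Nr4a1, transcription factors that are also on the immediate early list, fell and Ly6c2, a surface marker of inflammatory monocytes, rose, the last being uncertain because of its paralog Ly6c1. Without WT replicate 1, WT replicate 4 or KO replicate 4, 0 of these passed in edgeR, and Nr4a1 also lost its call without WT replicate 3 (adjusted p = 0.0586), and Ly6c2 without WT replicate 3 or KO replicate 2 (adjusted p = 0.071 and 0.0535). DESeq2 called 2 higher and 4 lower and limma 2 and 2. Their median log2 fold change was 0.03 and their mean -0.10 (camera adjusted p = 0.597). Of 16 tissue macrophage genes, Siglec1, a sialic acid receptor, fell by 1.05 on the log2 scale (list adjusted p = 0.362), and DESeq2 and limma called 3 each as lower. In edgeR 3 fell without KO replicate 2. The list median was -0.08, and -0.24 without WT replicate 3. Of 16 endothelial genes, Eng, a co-receptor for transforming growth factor beta, fell by 0.46, a call lost without WT replicate 1, 3 or 4 (adjusted p = 0.130, 0.0555 and 0.166) and without KO replicate 3 or 4 (adjusted p = 0.0602 and 0.170), while the median was -0.0027 and the mean 0.09 (list adjusted p = 0.725). In each of the lists that follow, the last being the sex-linked genes, 0 genes passed in edgeR over all 6 libraries. Stem and progenitor genes had a median of -0.05 (adjusted p = 0.512), 2 genes at an unadjusted p under 0.05, 2 in DESeq2 and 1 in limma. Dendritic cell genes had a median of -0.25 (adjusted p = 0.0671), with 3, 2 and 1 genes by the same measures. T and NK cell genes had a median of -0.06 (adjusted p = 0.873), with 2, 1 and 1. Megakaryocyte genes had a median of 0.19 (adjusted p = 0.362), with 0 by each. Genes of basophils, mast cells and eosinophils had a median of 0.14 (adjusted p = 0.909), with 5, 2 and 1. Genes of marrow stroma and bone had a median of 0.10 (adjusted p = 0.228), with 2, 2 and 0. The 5 sex-linked genes had a median of -0.09 (adjusted p = 0.462), with 1, 0 and 0. Without KO replicate 2, 3 stem and progenitor genes, 1 dendritic cell gene and 1 megakaryocyte gene fell and 1 T and NK cell gene rose. Without WT replicate 1 the medians of the stem and progenitor (0.09), T and NK cell (0.09) and basophil (-0.09) lists changed sign. Some of the remaining cell type lists passed camera in other settings. The dendritic cell list did so downward without WT replicate 3 (adjusted p = 0.0112), without WT replicate 4 (adjusted p = 0.0235), without KO replicate 2 (adjusted p = 0.000980), with no filter on low counts (adjusted p = 0.0276) and at a mean log2 CPM of at least 1 (adjusted p = 0.0486), whereas its median was -0.08 without WT replicate 1, -0.09 without KO replicate 3 and -0.11 without KO replicate 4. The megakaryocyte list passed upward without WT replicate 1 (adjusted p = 0.0224) and without KO replicate 3 (adjusted p = 0.000944), and without WT replicate 4 so did the lists of stroma and bone (adjusted p = 0.000614) and of endothelial cells (adjusted p = 0.00609).

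The pathway lists other than those above and the literature targets of miR-181, given below, did not pass camera over all 6 libraries. Angiogenic factors had a median of 0.02 and a mean of -0.07 over 22 genes (adjusted p = 0.605), and Ccl2 alone fell. Without KO replicate 2, 2 of the list fell and 1 rose. Vegfa, the main endothelial growth factor, had a log2 fold change of 0.31 ± 0.11 (SE, adjusted p = 0.135). Among 20 LXR and lipid genes (adjusted p = 0.152) Abca1, a cholesterol exporter, fell by 0.59, a call lost without WT replicate 1, 3 or 4 (adjusted p = 0.0898, 0.0555 and 0.0808) and without KO replicate 4 (adjusted p = 0.0784), and DESeq2 called 2 and limma 1 as lower. Among 19 heat shock and unfolded protein genes (adjusted p = 0.112) Hspa1a fell and Xbp1 rose, with a median of 0.36, while DESeq2 called 4 higher and 2 lower and limma 2 and 2. That list passed camera upward without WT replicate 1 (adjusted p = 0.0224), without KO replicate 2 (adjusted p = 0.000224, 5 higher and 1 lower) and with no filter on low counts (adjusted p = 0.0243). The LXR list passed downward at a mean log2 CPM of at least 1 (adjusted p = 0.0486) and with the Xist covariate (adjusted p = 0.0318). In 4 lists 0 genes passed in edgeR. Interferon-stimulated genes had a median of -0.07 (adjusted p = 0.611, but adjusted p = 0.0156 downward without WT replicate 4), with 3 genes at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma. Cell cycle genes had a median of -0.07 (adjusted p = 0.362), with 3, 1 and 1 by the same measures. Cholesterol synthesis genes had a median of -0.10 (adjusted p = 0.315), with 6, 3 and 1. Mitochondrially encoded genes had a median of -0.06 (adjusted p = 0.559, but adjusted p = 0.0185 downward after removal of the length and GC trend), with 1, 1 and 1.

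Loss of a microRNA can relieve its targets of repression, so the comparison of KO with WT also asked whether genes carrying miR-181 sites differed. Mature miR-181a and miR-181b were not measured, so whether and how far their levels fell in KO marrow is unknown. Of 20 measured targets named in the literature, 2 fell, 0 rose and 18 did not pass, and over the list alone 6 fell and 1 rose. DESeq2 called 6 lower and 1 higher and limma 3 lower and 1 higher. Those that fell were Cd69, at 75.1 ± 12.1 CPM in WT and 19.7 ± 3.06 CPM in KO (SD, n = 3 each), and Dusp5, a phosphatase of MAP kinases, by 1.17 on the log2 scale. Lin28a, an RNA-binding protein, had a log2 fold change of 0.42 (adjusted p = 0.0502) and Klf6, which is also on the immediate early list, of -0.45 (adjusted p = 0.0625). The median was -0.10 (camera adjusted p = 0.00323, fry adjusted p = 0.0342, adjusted p = 0.196 with an estimated correlation). The number that fell was 1 without WT replicate 1, 1 without WT replicate 4, 1 without KO replicate 4 and 4 without KO replicate 2, and the median was -0.17 without WT replicate 1, without WT replicate 3 and without KO replicate 2.

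Genes with a miR-181a/b-5p site in an annotated 3' UTR were lower in KO, not higher. The 869 tested genes with the 8mer site TGAATGTA had a median log2 fold change of -0.0749. Random genes without a 6mer site, matched on expression and 3' UTR length, had a median of -0.0197 (95% range -0.0422 to 0.0021), a difference of -0.0553. Against all genes without a 6mer the set passed camera (p = 0.000295, but p = 0.070 with an estimated correlation), and against no change it passed fry (p = 0.0254). Of the 869 genes 5 rose and 22 fell, against 112 and 120 of the 8563 genes without a 6mer. The 2631 genes with the 7mer site TGAATGT differed by -0.0286 from matched genes, with 17 higher and 59 lower (camera against all genes without a 6mer p = 0.00541, p = 0.0996 with an estimated correlation, fry against no change p = 0.0519). After removal of each library's trend on exon length and GC content the 8mer difference was -0.0279 and the call was lost (camera with the preset correlation, p = 0.623). For comparison, 6 of 100 shuffled 8mers, each set against matched genes without its own 6mer, gave a difference at or below the -0.0553 of the site. Set against matched genes without the 8mer itself, the site gave -0.0365, and 13 of 100 shuffled 8mers gave a difference at or below that.

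**Figure D3:**
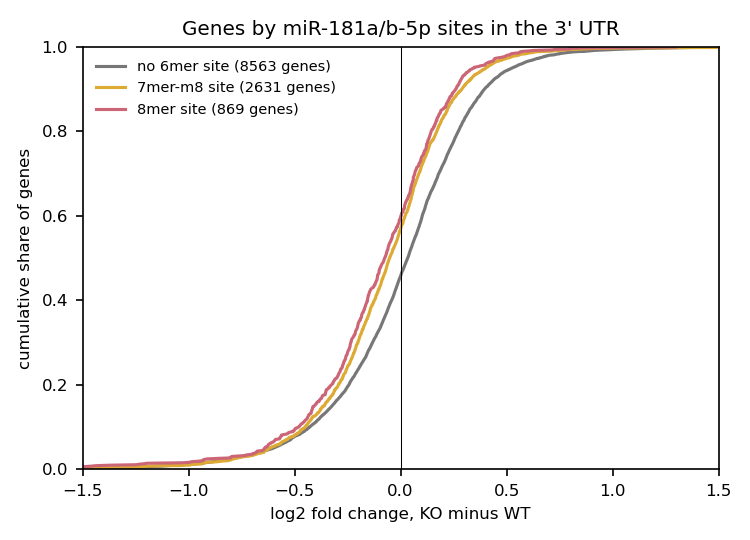
Cumulative share of genes (y axis) by log2 fold change, KO minus WT (x axis, drawn from -1.5 to 1.5), for genes with an 8mer site (red, 869), a 7mer-m8 site (yellow, 2631) or no 6mer site (grey, 8563). The curves of genes with sites lie to the left of the grey curve, the 8mer median being -0.0749.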

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

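The Xist covariate and the removal of the length and GC trend were chosen after seeing the data. None of the 417 genes changed sign in any setting in which it was tested. They were chosen for passing in these same libraries, so this is no measure of their reliability. Against 417 genes (159 higher, 258 lower), no filter on low counts gave 1492 (653 and 839), DESeq2 1641 (857 and 784), limma 1057 (495 and 562) and the Xist covariate 209 (76 and 133), while library totals gave 87 higher and 403 lower. The cause was not tested. Leaving out 1 library gave between 32 and 920 genes, between 6 and 316 higher and between 23 and 604 lower, with fewer samples in each fit. Of 12 lists past camera, 0 passed with an estimated correlation and 4 in fry. With unchanged medians, the estimated correlation ended the calls of the primary granule (0.57), late neutrophil (0.49), mature B cell (-0.83), erythroid (-0.33), NF-kB (-0.44) and immediate early (-1.23) lists. The calls of the late neutrophil (0.49), mature B cell (-0.83) and erythroid (-0.33) lists also ended in fry. These tests allow for more correlation between genes or compare no other genes, but the cause of the losses was not tested. The 8mer call was lost after removal of the length and GC trend (-0.0279, the cause was not tested) and with an estimated correlation (-0.055). It was kept in each fit that left out 1 library. For single genes and other lists, 2123 values kept direction and side of the threshold, 188 passed newly and 167 no longer passed.

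The replicate numbers 3 and 4 occur in both groups. The deviations of the 2 samples correlated at 0.21 for number 3 and at -0.139 for number 4, and nothing in the labels says whether the numbers pair the samples, which were therefore compared unpaired. Number 1 occurs only in WT and number 2 only in KO. With the replicate block, only the samples numbered 3 and 4 therefore inform the difference between genotypes. In that fit 571 genes passed, 210 of them among the 417, with 1 residual degree of freedom against 4. The B cell precursor median was -1.40 with 16 lower, and late neutrophil calls numbered 0 against 4. The dendritic cell (0.00419), heat shock (1.9e-06), stroma and bone (0.00214) and sex-linked (0.00640) lists passed camera by adjusted p. At this depth, a count of 0 allows up to 0.0886 CPM. The self-test recovered 22.0% of 1.5-fold changes, so many changes of that size or smaller may have been missed. Some of the 417 genes nevertheless changed by less than 1.5-fold.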

Other observations

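The tests of cell type loss and of scaling and both tests of the site-bearing genes were chosen after the result was seen, as were the Xist covariate and the removal of the length and GC trend. Xist, the RNA that silences an X chromosome, was present in 3 libraries across both groups, at 3.497 CPM in WT replicate 3, 5.05 CPM in WT replicate 4 and 6.64 CPM in KO replicate 2, and at 0.147, 0.220 and 0.0758 CPM in WT replicate 1, KO replicate 3 and KO replicate 4. The sum of 4 Y-linked genes in these 3 libraries was 1.04 times that in the other 3. The split of the 6 libraries by Xist called 1 gene, Xist itself, and 899 at an unadjusted p under 0.05. These values were first set out as tests of animal sex and of a technical batch and are given here without weighing.

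Among genes outside the lists, Igkc, the kappa light chain constant region, rose from 575 ± 71.0 CPM to 1007 ± 92.9 CPM (SD, n = 3 each, edgeR adjusted p = 0.0215). The medians of the B cell lists were negative, whereas that of the plasma cell list was 0.47. The call of Igkc was lost without WT replicate 1 (adjusted p = 0.0745), without WT replicate 4 (adjusted p = 0.0830) and without KO replicate 4 (adjusted p = 0.0799). Igkc was chosen after its values were seen.

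With 10 splits of 3 against 3 libraries no share under 0.05 can be reached. The real split gave 417 genes, and the highest of the other splits 1, so 1 of 10 gave as many. For lists, the real split gave 12 and the highest other 18, and 4 of 10 gave as many. The number of lists past camera is therefore not particular to the genotype split, and camera calls of lists alone do not tie their directions to genotype. For the 8mer difference, the real split gave 0.055 in size and the highest other 0.048, so 1 of 10 was as large. By the camera test of the 8mer genes, however, some splits that mix the genotypes passed more strongly than the real split. These set apart WT replicates 1 and 3 with KO replicate 3, WT replicates 1 and 4 with KO replicate 3, and WT replicate 1 with KO replicates 2 and 4. The other mixed splits did not pass. The camera call of the 8mer genes is therefore not particular to the genotype split.

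Lower immediate early genes in KO may reflect genotype or how the marrow was handled. Exon length and GC bias as the whole cause is argued against, since the median after removal of the trend was -1.23. Loss of a cell type that carries these transcripts stays open. In 0 of 17 cell type lists was the mean fall as large with no overlap between the libraries of the groups. The lowest bound of a list median, -1.15, lay within the interval of the immediate early median (-1.70 to -0.68), but it was that of skeletal muscle, whose genes lay at or below 8.06 CPM on average in WT, against 1563 CPM for Fos. Longer handling of WT marrow before lysis also cannot be told apart from genotype, because the 4 heat shock genes had a median of -0.56 with Hspa1a lower (adjusted p = 0.0358) and Hsph1 at 0.15. That median replaced a count of genes as the test's value after the 4 values were seen. Handling times were not used here, and a biological effect of the deletion is untested beyond the genotype itself.

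Higher neutrophil with lower B cell and erythroid genes in KO may likewise reflect cell composition. The late neutrophil median exceeded the mean of the B cell and erythroid medians by 1.07, and by 0.902 without KO replicate 4 and 1.04 after removal of the length and GC trend, which argues against either as the whole cause of the difference in medians. The calls of single late neutrophil genes were nevertheless lost in both settings (0 against 4). Other single libraries were not tested as the cause. Without WT replicate 1 the medians were 0.39 (late neutrophil), -0.64 (B cell precursor), -0.46 (mature B cell) and -0.17 (erythroid). Scaling by a few abundant genes is also argued against as the whole cause of the difference between the lists. A single factor per library moves both lists alike, whereas the late neutrophil median was 0.49 and the erythroid median -0.33. Their intervals (0.34 to 0.61 and -0.51 to -0.30) lay apart by 0.639, but they resample genes and do not measure the spread between libraries. The test set beforehand compared the difference of these medians, 0.824, with that under other scalings, of which the smaller was 0.821. It could not come out otherwise and was set aside for the comparison of intervals after its value was seen. Cell composition and a biological effect of the deletion stay open, as untested.

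Lower genes with 8mer sites in KO run opposite to relief from repression. Mature miR-181 was not measured, so the extent of any such relief is unknown. A/T-rich 3' UTRs whatever the motif is a candidate explanation, since 6 of 100 shuffled 8mers, each set against matched genes without its own 6mer, gave a difference at or below the -0.0553 of the site, near the bound of 5 set for this test. Their mean was -0.0285. Length and GC bias stays open: after removal of the trend the difference was -0.0279 and the set no longer passed (camera with the preset correlation, p = 0.623), which met the first criterion for that explanation. A further condition, a median within the range of matched lists, was added once this was known, and the median of 0.0218 lay below that range (0.030 to 0.067).

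Higher Fkbp5 may point to more glucocorticoid signalling in KO marrow, a hypothesis tested on 13 other glucocorticoid-induced genes listed before the test. Their median was 0.0599, with a 95% interval from -0.08 to 0.51, 7 of 13 were positive and Cebpd alone passed, a call lost without WT replicate 1, 3 or 4 and without KO replicate 4. The criterion set beforehand, a positive median and a camera p under the threshold, was met (p = 0.0241), but not with an estimated correlation (p = 0.189) or in fry (p = 0.0876). A requirement that the interval lie above 0 was added after the value was seen, and with it the hypothesis stays open. The members lay on both sides of 0, with log2 fold changes of 1.33 ± 0.26 (SE, edgeR adjusted p = 0.0563) for Il1r2, 0.74 for Errfi1, 0.58 for Cdkn1c and 0.50 for Klf9, against -0.08 for Tsc22d3, -0.05 for Zbtb16 and -0.32 for Mt2.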
